A study of Mus musculus with 15 samples.

How the data were processed

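Aortic valve leaflets, 3 per mouse, were dissected from 15 mice of 4 groups and treated with collagenase for 20 minutes at 37 °C before RNA isolation, per the labels' protocols. Complementary DNA was made with random and oligo-dT primers and amplified by a linear, single-primer isothermal method (NuGen Ovation RNA-seq V2), per the labels' protocols. Amplification from small amounts of RNA adds noise to genes with low levels, and this kit does not keep the strand, so that reads of antisense or overlapping genes cannot be told apart. Paired-end reads of 100 bp came from an Illumina HiSeq 2500 with 4 libraries per lane, per the labels' protocols. The lane and date of each library are not given in the sources used here, so no batch could be examined.

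FastQC, TopHat, SAMtools, Picard and the mouse build mm9 are named in the submitters' processing notes, without versions or roles. The tool that made the expression values, the gene annotation and the test behind the calls are not given in the sources used here. The authors deposited 1 FPKM value per gene and group, per the file headers, so the libraries of a group were pooled or averaged before deposit and neither their spread nor their depth is known. The deposited table also holds 5 columns of 0 or 1, named for pairs of groups in the file headers, which are read here as the authors' calls of different genes. Columns 8 and 9 share a header. They were assigned to comparisons by the FPKM values: for each call column, 1 pair of groups alone had at least a 4-fold ratio in every called gene.

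The groups were fixed from the genotype labels before the data were examined, as were the comparisons, 29 gene lists, the rule for named genes and the first set of alternative settings. The planned tests needed values per library and were replaced, as planned for a table of the authors' own comparisons, by a description of the authors' calls. No p-value, error or interaction test is given, and the differences have no replicate check. Log2 folds were computed as log2(FPKM + 1) of 1 group minus that of the other. The median log2 fold of all genes was 0.09 and 0.06 for the Notch1 genotypes with long and short telomeres. It was -0.23 and -0.24 for short against long telomeres in Notch1 wild type and heterozygous valves, and -0.16 for the group with both changes against the group with neither. List medians and means are relative to these values.

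For each list the median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these pooled values. Members of a list can vary together between mice, which random lists do not capture, so lists can fall outside the central 95% more often than the 1.45 of 29 that independent genes would give. On simulated data for 18073 genes with an SD of 1, 6.38% of 580 unchanged lists fell outside the central 95% and 85.9% of lists shifted by 1 on the log2 scale were found. All 6 simulated call columns were traced to the right pair of groups. Their flags were drawn from genes past 4-fold in the true pair, so this checks the code and not the assignment of the real columns.

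Another 8 lists were written after the table was seen: platelets, thymocytes, thymocyte stage genes, B cells, neutrophils, atrial genes, circadian clock, and haem and iron handling. The rule for named genes was adapted, since it ranked by adjusted p. It took Notch1 and Terc, up to 10 called genes per direction with the largest log2 fold and without a clone or predicted name, and the 4 members with the largest folds of the Notch, osteoblast, chondrocyte, mineralisation inhibitor, inflammatory, p53 and telomerase lists and of fixed lists outside the central 95%. Of these list members a part is named in the text. Other genes were chosen after their values were seen, and a few genes that the rule names are not reported here.

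Symbols were matched by identifier to GENCODE annotation of build GRCm38 for 16962 of 18073 genes, 93.9%, and exon lengths were taken from it. That build differs from the one in the submitters' notes, so no coordinates are given. A value of 0 in such a table can be a failed estimate, and genes are only said to be listed at 0. The table lists 705 and 250 genes at 0 in wild type and heterozygous valves with long telomeres, and 2010 and 1181 with short telomeres. Alternatives were a pseudocount of 0.1, minimum FPKM values, median scaling, scaling without mitochondrial genes, and leaving out genes of other cell types. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.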

Results

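RNA was sequenced from aortic valve leaflets of C57BL/6 mice aged 2 months. The mice carried 2 or 1 working copies of Notch1, a receptor needed for normal aortic valve development, in the setting of long or short telomeres. Long-telomere mice had intact Terc, the gene for the RNA template of telomerase, and short-telomere mice were generation 2 Terc nulls. There were 15 libraries, 1 per mouse, from 3 leaflets each: 4 from Notch1 wild type and 4 from Notch1 heterozygous mice with long telomeres, and 3 from wild type and 4 from heterozygous mice with short telomeres. The title of the series poses the question of whether telomere length alters the outcome of losing 1 copy of Notch1. The table used here gives 1 FPKM value (fragments scaled to transcript length and to the total of fragments) per gene and group for 18073 genes, so the spread between mice is unknown and no value below carries an error. It also marks, for 5 pairs of groups, the genes that the authors called different. Read depth per library is unknown. Each FPKM below is the authors' pooled value, and each log2 fold is on the log2(FPKM + 1) scale, which understates the change of genes with low values.

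Terc (ENSMUSG00000064796) was listed at 0 in both short-telomere groups, against 1.42 FPKM in wild type and 4.52 FPKM in heterozygous valves with long telomeres. Notch1 (ENSMUSG00000026923) stood at 39.1 FPKM in wild type and 25.1 FPKM in heterozygous valves with long telomeres, a log2 fold of -0.62. With short telomeres the order was the other way round, with 16.6 FPKM in the group labelled wild type and 23.3 FPKM in the group labelled heterozygous, a log2 fold of 0.47. Notch1 and Terc were not among the genes called in any of the 5 comparisons of the authors' deposited table. The labels do not say which part of Notch1 the mutant allele lacks, so it is unknown whether the FPKM of the whole gene includes its transcripts. The 2 groups labelled Notch1 wild type, at 39.1 and 16.6 FPKM, were further apart than either pair of genotypes. The Notch1 level therefore cannot check the labels, and the groups with short telomeres are named below by them.

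Of the 18073 genes, 285 were called in at least 1 comparison of the authors' deposited table, and 0 in all 5. The number per comparison ranged from 75 for Notch1 heterozygous against wild type with long telomeres to 124 for short against long telomeres in Notch1 wild type. The smallest ratio among called genes lay between 4.25-fold and 4.79-fold in the 5 comparisons, and Notch1 differed by less in each. Random lists matched to the fixed lists held a mean of 0.02 to 0.26 calls. A list with 0 calls is therefore the usual outcome and does not speak against smaller shifts. The median log2 fold of all genes lay between -0.24 and 0.09 in the 5 comparisons, and the medians of gene lists below are given relative to it.

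**Figure D1:**
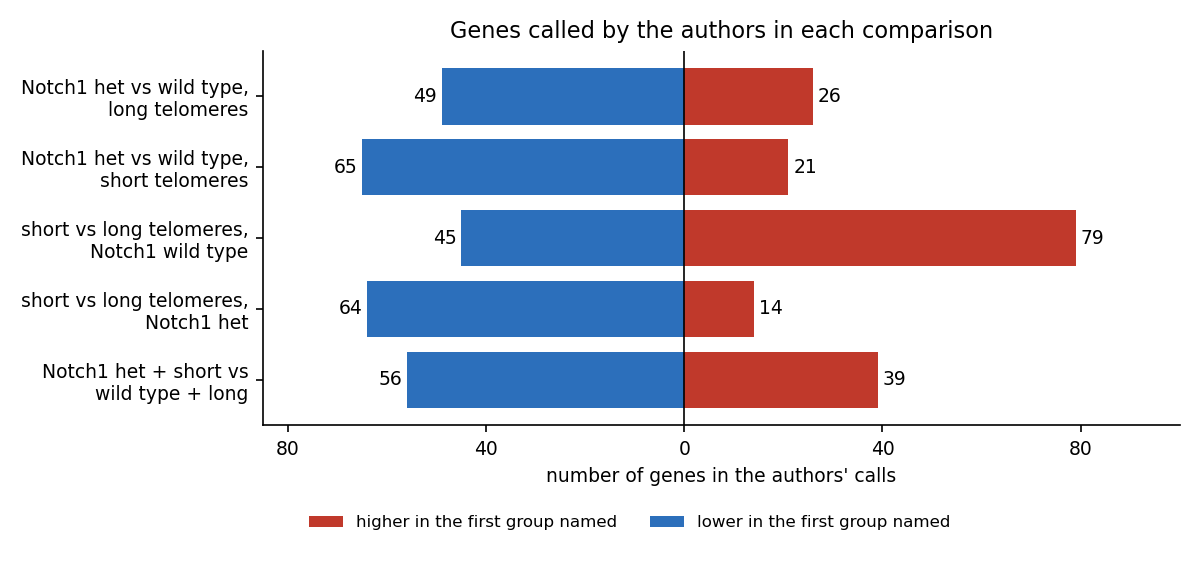
Number of genes called by the authors in each of the 5 comparisons (horizontal axis, genes), with genes higher in the first group named to the right and genes lower in it to the left. Lower genes outnumber higher ones in 4 comparisons, and in short against long telomeres in Notch1 wild type 79 genes are higher and 45 lower.

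With long telomeres, the leading difference in Notch1 heterozygous valves was a loss of platelet transcripts and a gain of transcripts of developing T cells. Gp9 and Gp1bb, subunits of the platelet receptor for von Willebrand factor, fell from 531 to 2.21 FPKM and from 95.1 to 0.863 FPKM. Ppbp, a platelet chemokine, fell from 1636 to 12.9 FPKM. Dntt and Rag1, which assemble antigen receptor genes in immature lymphocytes, rose from 10.9 to 139 FPKM and from 13.1 to 138 FPKM. The T cell genes Cd3g (4.44 to 115 FPKM), Cd8a (21.4 to 210.1 FPKM), Cd4 (11.6 to 93.6 FPKM) and Trbc1 (36.7 to 564 FPKM) rose with them. Contractile genes of smooth muscle also fell: Myh11, its myosin heavy chain, from 83.6 to 4.55 FPKM, Cnn1 from 50.7 to 4.06 FPKM and Myl9 from 314 to 28.5 FPKM. The wild type reference was the highest of the 4 groups for the smooth muscle list, with a mean log2(FPKM + 1) of 5.75. The mean was 3.86 in heterozygous valves with long telomeres, and 4.55 and 4.18 in wild type and heterozygous valves with short. For the atrial list the means were 5.30, 2.52, 2.34 and 4.26 in the same order. Differences in dissected tissue were not tested.

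The authors' deposited table called 75 genes in that comparison, 26 higher and 49 lower in heterozygous valves. Of the 22 measured genes of a platelet list written after the table was seen, 21 were called lower, and of 21 thymocyte genes on a list of the same kind 10 were called higher. Without these lists and those of neutrophils and erythroid cells, 44 called genes were left. The other T cell genes among the largest rises were Traj43, a T cell receptor joining segment listed at 0 in wild type and at 414 FPKM in heterozygous valves, Tcrg-V2, Ccr7, Cd6 and Cd247. Fam169b and Syt13 were also among the 10 largest rises, and Ly6g6c, AU023871, Treml1, Tubb1, Alox12 and Nrgn among the 10 largest falls. Bmp10 and Myl7, which are atrial genes in the adult heart, fell from 35.9 to 0.162 FPKM and from 216 to 13 FPKM.

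Among the 29 gene lists fixed beforehand, 14 had a median outside the central 95% of random lists matched on expression. The list of smooth muscle and myofibroblasts had the lowest median, -2.02 relative to all genes, with 5 of 15 members called lower in the authors' deposited table. Of the 18 chondrocyte-associated genes 0 were called, where matched random lists held a mean of 0.07 calls. Of the same genes 16 were lower, and their median was -0.81, below all 10000 random lists. Cilp2 stood at 14.4 FPKM in wild type and 2.29 FPKM in heterozygous valves, Cilp at 42 and 9.68 FPKM, and Acan, the cartilage proteoglycan aggrecan, at 3.72 and 0.449 FPKM. Of 21 collagen, elastin and proteoglycan genes of the valve matrix 20 were lower (median -0.72, 0 called), with Col5a1 at 54.2 and 22.6 FPKM and Eln at 39.3 and 18.1 FPKM. The Notch list had 13 of 16 members lower and 0 called (median -0.56, above 0.29% of random lists), beside endothelial markers with 12 of 16 lower and 0 called (median -0.36). Its members with the largest folds were the ligand Dll1 (7.97 and 2.85 FPKM), the target Heyl (28.2 and 13.9 FPKM), Notch2 (43 and 21.6 FPKM) and Dtx1 (3.65 and 1.42 FPKM). Markers of valve interstitial cells and fibroblasts (15 of 16 lower, median -0.91, 0 called), mesothelium (9 of 12 lower, median -1.39, 0 called) and erythroid cells (8 of 9 lower, median -1.23, 0 called) were low in the same group.

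Beside the thymocyte list (median 2.74), the cell cycle list was higher in all 21 members (median 1.77) with 1 called in the authors' deposited table, the cyclin Ccnb2 (2.1 to 29.4 FPKM); Plk1 was at 0.988 and 11.4 FPKM. The 20 inflammatory genes held 1 call, the chemokine Ccl7 (2.61 to 30.8 FPKM), and Ccl2, Tnfaip3 and Il1b stood at 46.2, 60.5 and 69.8 FPKM against 9.97, 10.9 and 31.2 FPKM. All 18 telomerase and shelterin genes were higher (median 0.41, 0 called), among them Terf1 at 5.58 and 17.7 FPKM and Nop10 at 23.3 and 53.3 FPKM. That list fell within the central 95% among genes with a mean FPKM of at least 10, where its median was 0.47. The osteoblast-associated list lay inside the central 95% (0 of 12 called), its median turning from 0.04 as deposited to -0.05 relative to all genes, with Bglap2, an osteocalcin gene, at 0.227 and 3.79 FPKM and Msx2 at 3.82 and 0.966 FPKM. The mineralisation inhibitors were also inside (median -0.41, 0 of 10 called), with Smad6 at 25.8 and 11.1 FPKM, as were the p53 targets (median 0.27, 0 of 18 called), with Trp53inp1 at 8.16 and 40.5 FPKM.

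**Figure D2:**
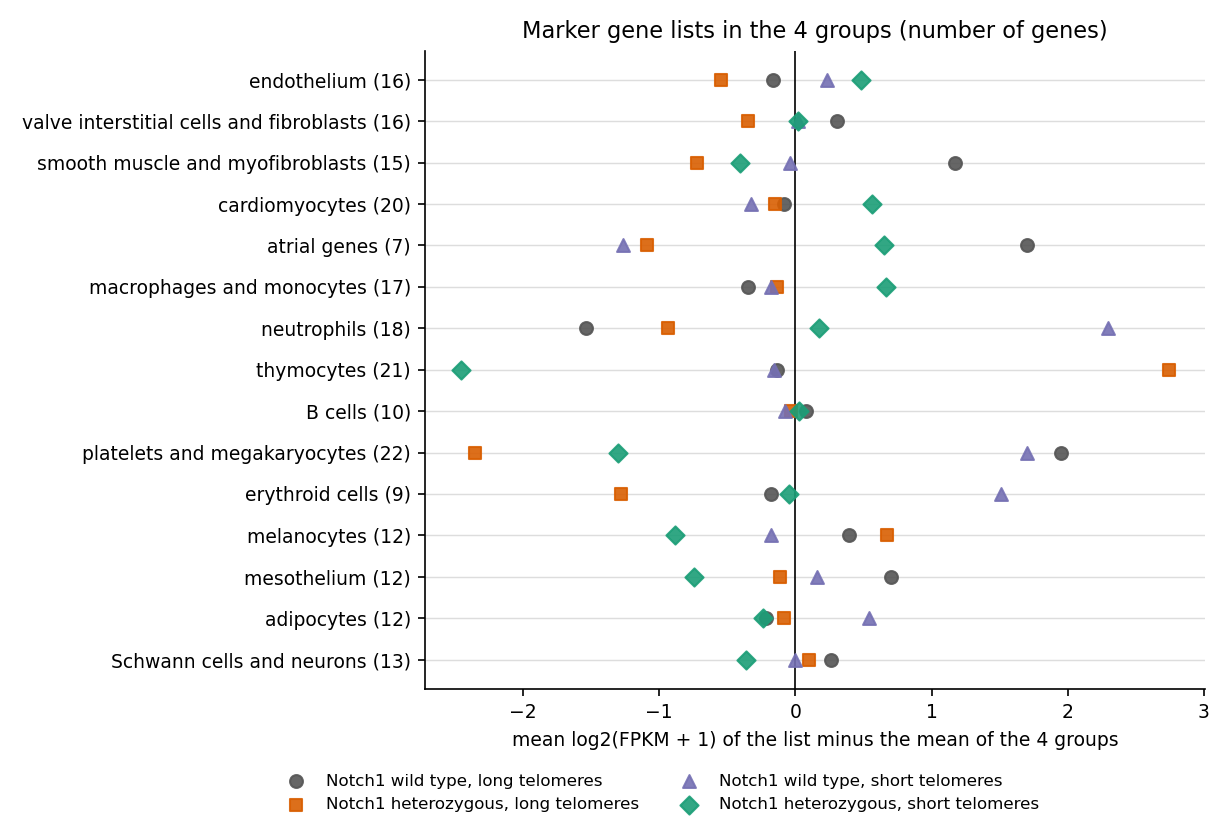
Mean log2(FPKM + 1) of marker gene lists in each of the 4 groups (points), as the difference from the mean of the 4 groups (horizontal axis, log2 units), with the number of genes per list in parentheses. Thymocyte genes are highest in Notch1 heterozygous valves with long telomeres, neutrophil genes in wild type valves with short telomeres, and platelet genes are low in both heterozygous groups.

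With short telomeres, platelet transcripts were again lower in the valves labelled Notch1 heterozygous. Gp9 fell from 346 to 20.8 FPKM, Gp1bb from 80.1 to 2.55 FPKM and Gp5 from 18.2 to 0.187 FPKM. T cell genes fell in this setting, with Cd8b1 going from 46.9 to 1.39 FPKM, Arpp21 from 14.8 to 0.0223 FPKM and Cd8a from 32.5 to 1.43 FPKM. Neutrophil genes fell as well: S100a8, a subunit of calprotectin, from 892 to 77.4 FPKM and Retnlg from 163 to 6.68 FPKM. Tcf21, a transcription factor of epicardium-derived fibroblasts, rose from 1.01 to 20.1 FPKM, and Nrg1, a growth factor for heart muscle, from 0.588 to 18.3 FPKM.

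The authors' deposited table called 86 genes here, 21 higher and 65 lower in the heterozygous group. The calls held 14 of the 22 platelet genes, 9 of the 21 thymocyte genes, 3 of 18 neutrophil genes and 2 of 9 erythroid genes, all lower; 58 called genes were in none of these lists. Alb, the liver protein albumin, was listed at 0 in wild type and at 17.8 FPKM in heterozygous valves. Adamts8, a secreted protease, rose from 3.29 to 34.7 FPKM, and Slc25a15, Tnfrsf13c, Pla2g2d, Tmem106c, Fcrls and Piwil2 were the other large rises. Cd207, a marker of Langerhans cells, fell from 22.9 to 0.27 FPKM and Slamf1 fell from 43.2 to 1.77 FPKM. Igh-3 was listed at 22.3 FPKM and at 0. Of the 86 called genes, 23 stayed under 10 FPKM in both groups.

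Of the fixed lists 13 lay outside the central 95% of random lists. Macrophage and monocyte markers were higher in 13 of 17 members (median 0.82) with 0 calls in the authors' deposited table, with C1qa at 33 and 145 FPKM and Mrc1 at 15 and 47.6 FPKM. All 20 cardiomyocyte genes were higher (median 0.74, 0 called), and Nppa, the atrial natriuretic peptide, stood at 46.8 and 413 FPKM. The erythroid list was lower in 9 of 9 members (median -1.78), with Slc4a1 falling from 133 to 20.7 FPKM. All 12 mesothelial genes were lower (median -0.92, 0 called), as were 13 of 20 immediate early and heat shock genes (median -0.39, 0 called). The chondrocyte list was higher in 14 of 18 members (median 0.41, 0 called), with Chad at 59.6 and 167 FPKM and Acan at 0.0521 and 1.57 FPKM. It fell within the central 95% with a pseudocount of 0.1 (median 0.62) and among genes with a mean FPKM of at least 10 (median 0.33).

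The osteoblast-associated genes were inside the central 95% (median 0.22, 0 of 12 called) although 10 of 12 were higher. Spp1, the matrix protein osteopontin, stood at 8.63 and 130.2 FPKM and Bmp2 at 7.15 and 42.5 FPKM without a call. Notch genes were also inside (median 0.26, 0 of 16 called), with Lfng at 0.483 and 6.39 FPKM, Hey2 at 4.04 and 20.8 FPKM, Nrarp at 1.06 and 7.74 FPKM and Heyl at 26.5 and 8.06 FPKM. So were the mineralisation inhibitors (median 0.34, 0 of 10 called), with Mgp, the matrix Gla protein, at 2489 and 4568 FPKM. The inflammatory list (median 0.25, 0 of 20 called) had Ccl7 at 23.1 and 90.2 FPKM, and the p53 list (median -0.04 against a mean of 0.08, 0 of 18 called) had Gdf15 at 1.34 and 11.5 FPKM. Telomerase and shelterin genes were lower (12 of 18, median -0.43, 0 called), with the shelterin component Pot1b at 18.4 and 2.47 FPKM. That list was inside the central 95% among genes with a mean FPKM of at least 10 (median -0.62).

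In Notch1 wild type valves, short telomeres went with a rise of neutrophil transcripts. S100a8 rose from 4.99 to 892 FPKM, S100a9 from 6.41 to 648 FPKM and Retnlg from 0.088 to 163 FPKM. Slc4a1, the anion exchanger band 3 of red cells, rose from 18.2 to 133 FPKM. The atrial gene Bmp10 went from 35.9 FPKM to a listing at 0, and Tcf21 fell from 26.2 to 1.01 FPKM. The immediate early genes Fosb and Fos rose from 14.2 to 117 FPKM and from 54 to 295 FPKM. Mitochondrially encoded mt-Atp6, a subunit of the ATP synthase, rose from 2221 to 11607 FPKM, and the transfer RNA genes mt-Tf and mt-Te rose from 5558 to 32203 FPKM and from 3315 to 20156 FPKM.

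The authors' deposited table called 124 genes in this comparison, 79 higher and 45 lower with short telomeres. Among them were 12 of the 18 neutrophil genes and 3 of the 9 erythroid genes, all higher, and 0 of 22 platelet and 0 of 21 thymocyte genes; 109 called genes were in none of these lists. The other large rises included Stfa2l1 and Tcrg-V2, the cyclin Ccnb2 (2.1 to 90 FPKM), Igh-3, P2ry14 and Ly9. Drd2 fell from 18.8 to 0.0174 FPKM, Cxcr6 from 15.2 to 0.118 FPKM and Cntn2 from 16.7 to 0.486 FPKM, and Olfr1420, Cacna2d2, Sbk3 and Atpgd1 fell as well. Dbp, an output gene of the circadian clock, fell from 47.1 to 3.56 FPKM. Gm13340, a nuclear copy of a mitochondrial sequence, rose from 47.5 to 265 FPKM with the mitochondrial genes, and such copies can share reads. Both groups stayed under 10 FPKM for 48 of the 124 called genes.

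Of the fixed lists 10 lay outside the central 95%. Beside the neutrophil list (median 3.64), the inflammatory list was higher in 16 of 20 members (median 1.28) with 1 call in the authors' deposited table, Ccl7 (2.61 to 23.1 FPKM), while the cytokine Il1b stood at 31.2 and 165 FPKM. Immediate early and heat shock genes were higher in 17 of 20 (median 1.16, 2 called). The p53 targets had a median of 0.71 with 0 of 18 called, and the cell cycle inhibitor Cdkn1a, a standard p53 target, stood at 75.4 and 280.3 FPKM, Fas at 5.8 and 31.2 FPKM and Pmaip1 at 2.55 and 10.8 FPKM. That list was inside the central 95% among genes with a mean FPKM of at least 10 (median 0.46). Smooth muscle genes were lower in 14 of 15 members (median -1.08, 0 called), with Cnn1 at 50.7 and 10.4 FPKM. Matrix genes were lower in 17 of 21 (median -0.32, 0 called), with Col1a1, a chain of collagen I, at 199 and 61.3 FPKM and Col6a3 at 41.6 and 10.7 FPKM. The adipocyte list was higher in 10 of 12 members (median 1.31, 0 called), and fell inside among genes with a mean FPKM of at least 10 (median 0.93).

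Of 18 chondrocyte-associated genes 2 fell in the authors' deposited table, Cilp2 from 14.4 to 0.912 FPKM and Acan from 3.72 to 0.0521 FPKM, and the list as a whole was inside the central 95% (median -0.26). The matrix proteases and inhibitors had 2 of 16 called, Mmp9 (0.0905 to 9.44 FPKM) and Timp4 (0.921 to 15.2 FPKM), and Mmp9 is also on the neutrophil list. The Notch list was inside (median -0.23, 0 of 16 called), with Lfng at 6.84 and 0.483 FPKM, Hey2 at 18.1 and 4.04 FPKM and Dll4 at 2.34 and 7.58 FPKM. The mineralisation inhibitors were inside as well (median -0.01 against a mean of 0.05, 0 of 10 called), with the adenosine-producing enzyme Nt5e at 3.97 and 8.9 FPKM. For the osteoblast list (0 of 12 called) and the telomerase and shelterin list (0 of 18 called) the sign of the median turned with the scaling. Their medians were -0.05 and -0.03 as deposited and 0.18 and 0.20 relative to all genes.

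In Notch1 heterozygous valves, short telomeres went with a rise of Spp1 and a loss of T cell transcripts. The thymocyte list was highest of the 4 groups in the long-telomere reference of this comparison. Dntt fell from 139 to 0.198 FPKM, Cd8a from 210.1 to 1.43 FPKM, Rag1 from 138 to 2.01 FPKM and Myb, a transcription factor of immature blood cells, from 136 to 0.537 FPKM. Spp1 rose from 8.35 to 130.2 FPKM, Nppa from 43.4 to 413 FPKM and Acta1, the skeletal form of actin, from 25.4 to 176 FPKM. The macrophage and cardiomyocyte lists were highest of the 4 groups in the same short-telomere valves. Their mean log2(FPKM + 1) was 5.37 and 7.07 in the long-telomere reference, and 6.17 and 7.79 with short telomeres. Mitochondrial mt-Atp6 rose from 2050.2 to 11898 FPKM and mt-Tf from 3393 to 30698 FPKM. The platelet genes Gp9 and Ppbp rose from 2.21 to 20.8 FPKM and from 12.9 to 85.9 FPKM, levels still under the 346 and 849.9 FPKM of the wild type group with short telomeres.

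The authors' deposited table called 78 genes, 14 higher and 64 lower in the group labelled heterozygous with short telomeres. Of the 21 thymocyte genes 20 were called lower, and 56 called genes were outside the platelet, thymocyte, neutrophil and erythroid lists. The largest falls also held Arpp21, Ccr9, Cd8b1, Trbc1, Tcf7 (333 to 5 FPKM) and Tcrb-V13 (980.1 to 17.2 FPKM). The largest rises held Alb (0.273 to 17.8 FPKM), Vipr2, Pla2g2d and AU023871, with mt-Te (2686 to 17891 FPKM).

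Of the fixed lists 19 lay outside the central 95%, 16 of them high. Endothelial genes were higher in 16 of 16 members (median 1.25) with 0 calls in the authors' deposited table. Cldn5, a protein of endothelial tight junctions, stood at 2.33 and 17.8 FPKM and Kdr, the main receptor for vascular endothelial growth factor, at 9.87 and 41.9 FPKM. Macrophage and monocyte markers were higher in 16 of 17 members (median 1.02, 0 called). Immediate early and heat shock genes were higher in 16 of 20 (median 0.73, 0 called). Beside both the senescence-associated list was higher in 13 of 15 members (median 1.36, 0 called) and the inflammatory list in 18 of 20 (median 1.10, 0 called), with the cytokine Il6 at 0.51 and 11.6 FPKM and Cxcl1 at 35.1 and 164 FPKM in both. The Notch list was higher in 12 of 16 (median 0.78, 0 called), with Notch4 at 2.16 and 9.19 FPKM, Nrarp at 1.95 and 7.74 FPKM, Efnb2 at 20.3 and 53.1 FPKM and Dll4 at 1.96 and 6.39 FPKM. Chondrocyte-associated genes had a median of 0.84 with 0 of 18 called, Cilp standing at 9.68 and 31.8 FPKM and Chad at 57.2 and 167 FPKM, beside markers of valve interstitial cells and fibroblasts (11 of 16 higher, median 0.71, 0 called) and of smooth muscle (10 of 15 higher, median 0.59, 0 called). Spp1 was the only called member of the osteoblast list (8 of 12 higher, median 0.66) and of the mineralisation inhibitors (9 of 10 higher, median 0.68). Alpl, the alkaline phosphatase of mineralising cells, stood at 3.35 and 9.63 FPKM and Bmp2 at 18.9 and 42.5 FPKM.

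The cell cycle list was lower in all 21 members (median -2.01, 0 called in the authors' deposited table), with Plk1 at 11.4 and 0.245 FPKM. Telomerase and shelterin genes, which include Terc itself, were lower in 17 of 18 (median -0.77, 0 called), with Pot1b at 10.3 and 2.47 FPKM and Terf2ip at 11.6 and 3.88 FPKM. Melanocyte markers were lower in 11 of 12 (median -1.85, 0 called), with Dct at 75 and 11.3 FPKM. The p53 list had 11 of 18 members higher (median 0.58, 0 called), but Trp53inp1 stood at 40.5 and 10.4 FPKM and Bbc3 at 2.47 and 0.507 FPKM. These falls stand beside that of the thymocyte list, whose median was -4.75, and the rises beside that of the neutrophil list, whose median was 1.37 with 0 of 18 called. The reference group was itself high. Mean log2(FPKM + 1) of the cell cycle list was 2.43 and 4.26 in wild type and heterozygous valves with long telomeres, and 2.41 and 2.25 with short. In the same order the thymocyte list had 3.56, 6.44, 3.54 and 1.23, and the telomerase and shelterin list 2.77, 3.41, 2.80 and 2.38.

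**Figure D3:**
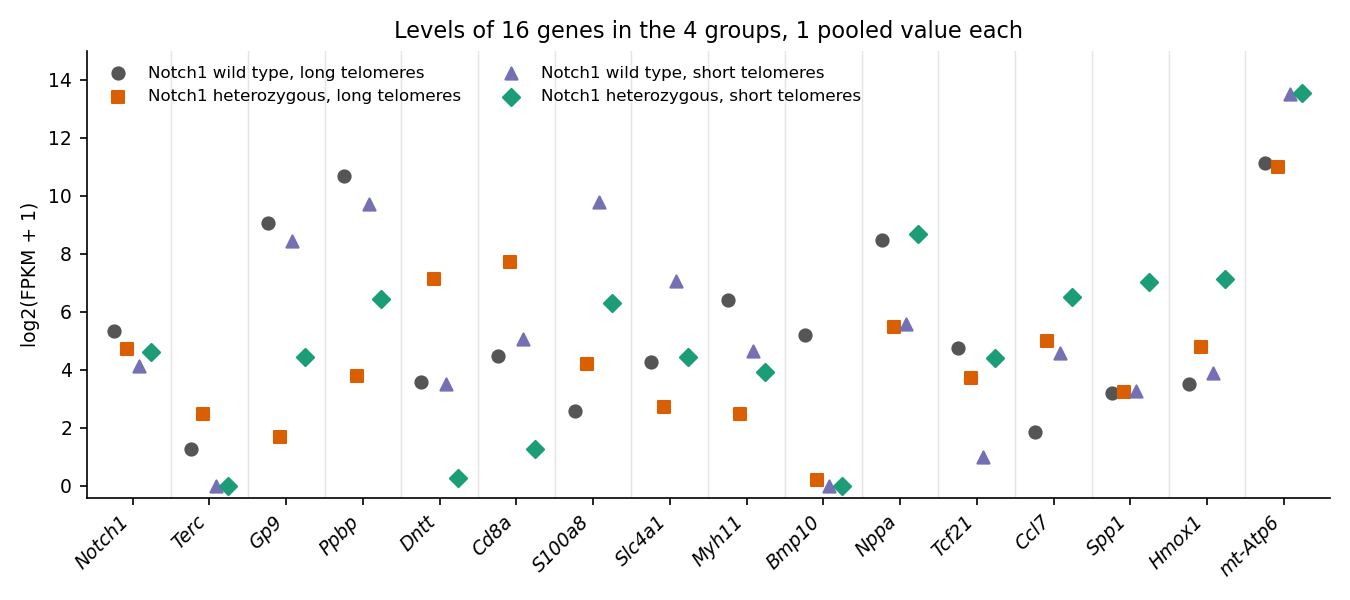
Level of 16 genes in the 4 groups on a log2(FPKM + 1) scale (vertical axis), 1 pooled value per group and no error bars because no values per library were used. Spp1 lies at 8.18, 8.35 and 8.63 FPKM in 3 groups and at 130.2 FPKM in valves labelled Notch1 heterozygous with short telomeres, while mt-Atp6 is high in both short-telomere groups.

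The valves with both changes, labelled Notch1 heterozygous with short telomeres, differed from those with neither by higher levels of genes of inflammation and of haem and iron handling, beside higher macrophage and monocyte markers (median 1.28). The authors' deposited table called 2 of 20 inflammatory genes and 2 of 12 genes of the haem and iron list, which was written after the table was seen. The monocyte chemokines Ccl7, Ccl2 and Ccl8 rose from 2.61 to 90.2 FPKM, from 9.97 to 106 FPKM and from 6.66 to 149 FPKM. Il10, an anti-inflammatory cytokine, rose from 0.382 to 28.3 FPKM. Hmox1, which breaks down haem, rose from 10.3 to 140.1 FPKM and Slc40a1, the iron exporter ferroportin, from 0.922 to 19.8 FPKM. Spp1 rose from 8.18 to 130.2 FPKM and Nppb, the B-type natriuretic peptide, from 5.55 to 89.3 FPKM. Platelet genes were lower again, with Gp9 falling from 531 to 20.8 FPKM and Ppbp from 1636 to 85.9 FPKM, and Cnn1 fell from 50.7 to 2.66 FPKM.

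The authors' deposited table called 95 genes, 39 higher and 56 lower. The calls included 16 of 22 platelet genes and 12 of 21 thymocyte genes, all lower, and 4 of 18 neutrophil genes, all higher; 63 were in none of these lists or the erythroid list. Alb (0.0777 to 17.8 FPKM), Sema3g (0.141 to 15.6 FPKM) and S100a8 (4.99 to 77.4 FPKM) were also among the 10 largest rises. Bmp10 (35.9 FPKM, then listed at 0), Gp1bb, Treml1, Gp6, Ly6g6c and Nrgn were among the 10 largest falls.

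Of the fixed lists 15 lay outside the central 95%. Beside the neutrophil list (median 1.69), the inflammatory list was higher in 17 of 20 members (median 1.45) with 2 called in the authors' deposited table, Ccl7 and Ccl2, and Cxcl1 and Il6 stood at 27.4 and 164 FPKM and at 1.91 and 11.6 FPKM. Immediate early and heat shock genes were higher with it in 17 of 20 (median 0.69, 0 called). The senescence-associated list (11 of 15 higher, median 1.09) had 2 called, Ccl2 and the matrix protease Mmp3 (6.41 to 47.9 FPKM). Macrophage and monocyte markers were higher in 15 of 17 (median 1.28, 0 called), with Cd14 at 22 and 122 FPKM and Lyz2 at 554 and 1839 FPKM. The p53 list was higher in 15 of 18 (median 0.86, 0 called), with Cdkn1a at 75.4 and 274 FPKM and Gdf15 at 2.03 and 11.5 FPKM. Endothelial genes had a median of 0.89 with 0 of 16 called. Smooth muscle genes were lower in 13 of 15 (median -1.22), with Cnn1, Lmod1 (30.6 to 3.06 FPKM) and Myl9 (314 to 64.9 FPKM) called.

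Osteoblast-associated genes had a median of 0.61, higher in 7 of 12, with 1 call in the authors' deposited table, Spp1. Bglap2 stood at 0.227 and 5.51 FPKM, Alpl at 1.18 and 9.63 FPKM and Bmp2 at 15.4 and 42.5 FPKM. The mineralisation inhibitors lay inside the central 95% (median 0.38, 1 of 10 called, again Spp1), with Mgp at 2835 and 4568 FPKM. Chondrocyte-associated genes were inside too (0 of 18 called), their median turning from -0.01 to 0.15 once the shift of all genes was taken off (mean -0.10), with Col11a2 at 10.9 and 1.11 FPKM and Cilp2 at 14.4 and 1.75 FPKM. Notch genes were inside (median 0.26, 0 of 16 called), with Heyl at 28.2 and 8.06 FPKM and Notch2 at 43 and 14.5 FPKM, and so were telomerase and shelterin genes (median -0.28, 0 of 18 called), with Pot1b at 8.98 and 2.47 FPKM. Melanocyte markers were lower in 11 of 12 (median -1.11), and Dct fell from 94.5 to 11.3 FPKM. Both factors differ in this comparison, so it cannot assign a change to either.

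The effect of Notch1 genotype was set side by side in the 2 telomere settings, which share no libraries. The authors' deposited table called 15 genes lower in heterozygous valves in both settings, where independent lists would share 0.176, and 0 genes higher in both. Most of the 15 were platelet genes such as Gp9, Ppbp, Itga2b and Treml1. Another 8 genes, among them Dntt, Cd8a and Trbc1, were called higher with long and lower with short telomeres. Across all 18073 genes the 2 sets of log2 folds had Pearson's r of 0.035 and Spearman's rho of 0.066, where genes are not independent replicates. With short telomeres Notch1 was higher in the group labelled heterozygous, but its level cannot show whether the labels are right. Were these labels exchanged, the 8 genes would be called higher in both settings, the 15 in opposite directions, and both correlations would change sign. The effect of short telomeres in the 2 Notch1 genotypes gave 5 genes called higher in both (mt-Atp6, mt-Tf, mt-Te, Gm13340 and Vipr2), 2 called lower in both and 2 called in opposite directions, with r of 0.180 across all genes. The interaction of genotype and telomere setting was not tested, because the table holds 1 value per group.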

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

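All tests of explanations in this part were chosen after the result was seen. The authors' deposited table called 8 genes higher in Notch1 heterozygous valves with long telomeres and lower with short telomeres. The difference of their log2 folds, short minus long, was -7.76 for Cd8b1, -7.52 for Trbc1, -7.33 for Cd6, -7.06 for Arpp21, -7.02 for Cd8a, -6.80 for Dntt, -6.56 for Ccnb2 and -6.04 for Chrna9. These differences rest on the short-telomere labels, which the Notch1 level cannot check. With the labels exchanged, all 8 genes would be higher in heterozygous valves in both settings. For Cd6 and Chrna9 the calls for short against long telomeres were also opposite in the 2 Notch1 genotypes. Their differences, heterozygous minus wild type, are the same contrast and so equal the values above, -7.33 and -6.04. Chrna9, a subunit of a nicotinic acetylcholine receptor, stood at 0.159, 9.54, 6.61 and 0.0544 FPKM in wild type and heterozygous valves with long telomeres and in the same order with short telomeres. The difference was not tested for any of these genes, because there is 1 pooled value per group, and for the same reason no library could be compared with others of its group.

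Thymocyte genes were high in Notch1 heterozygous valves with long telomeres. Thymus cells in the dissected tissue are a candidate source. The 5 genes of immature thymocytes that mature T cells lack had a median of 3.08, while B cell genes had -0.23. All 5 are on the thymocyte list, were chosen after the table was seen, and 3 were called higher here. Their height therefore restates the pattern and does not test this source. The T cell receptor genes Tcrb-V13, Trbc1 and Traj43 reached 980.1, 564 and 414 FPKM. Of the 21 list genes 6 are also in a fixed list and 20 were called in at least 1 comparison, and the labels name no sort that would remove such cells. An effect of losing 1 Notch1 copy in either telomere setting stays open. With short telomeres the thymocyte list had a median of -2.47 by the labels, which the Notch1 level cannot check there. With the labels exchanged the median would be 2.47. An effect of Notch1 that depends on telomere length also stays open and was not tested.

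Platelet genes were low in both groups labelled Notch1 heterozygous, and the erythroid list was low with them, in 8 of 9 members with long telomeres and 9 of 9 with short. The Notch1 level cannot check the labels with short telomeres. With these exchanged, both lists would be high in heterozygous valves there, and the pattern would not hold in both settings. The erythroid shift was smaller. With long telomeres its median was -1.23 (quartiles -1.52 and -1.14) against -4.08 for platelet genes (quartiles -5.20 and -3.39). With short telomeres it was -1.78 (quartiles -2.01 and -1.23) against -3.39 (quartiles -3.68 and -2.43). The platelet list was written after the table was seen, from genes that lead the calls, which can inflate its size. This gap therefore cannot decide whether less whole blood was the sole cause. Platelet list members called in the other Notch1 comparison, which shares no libraries, had medians of -5.05 (14 genes, upper quartile -3.59) with long and -3.35 (21 genes, upper quartile -2.41) with short telomeres. They come from the same list, so they do not remove this selection. For both changes against neither, the fixed erythroid list did not fall (median -0.01, quartiles -0.16 and 0.33), with 4 members higher and 5 lower. Platelet genes had a median of -2.90 there (quartiles -3.99 and -2.55). These values argue against less whole blood as the sole cause in that comparison, though the platelet list was selected as stated. Less blood as part of the cause, or as the sole cause within a telomere setting, stays open. So does an effect of Notch1 heterozygosity on platelets in either telomere setting: the platelet list had a median of -0.04 between the 2 wild type groups and 1.24 between the heterozygous groups, but all 22 genes were called in at least 1 comparison and 0 are in a list fixed beforehand, so these values restate the pattern. Platelet clots in single wild type libraries cannot be told apart from it, because the table has 0 columns with values of a single library.

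Mitochondrially encoded genes were high in both short-telomere groups: 24 measured genes, 20 of them transfer RNA genes, had medians of 0.97 in Notch1 wild type and 2.43 in heterozygous valves relative to all genes, with lower quartiles of 0.55 and 2.20. The authors' deposited table called 3 of the 24 in wild type, where 21 were higher, and 4 in heterozygous valves, where all 24 were. The reference group of the second value was itself low: with long telomeres 0 of 24 were higher in heterozygous than in wild type valves (median -0.69), and both changes against neither gave a median of 1.63. In heterozygous valves 25 nuclear genes no longer than the longest of these transfer RNA genes had a median of -0.67 (upper quartile -0.08). They argue against a length-dependent distortion of short transcripts there. The nuclear oxidative phosphorylation list rose less than the mitochondrial genes, in 15 of 21 members, with a median of 0.38 and an upper quartile of 0.58. Its reference group was itself high: with long telomeres 21 of 21 members were higher in heterozygous than in wild type valves (median 0.43). Both changes against neither gave a median of 0.80 for it, with 20 of 21 higher. A joint rise of nuclear and mitochondrial respiratory genes, unequal in size, therefore stays open. In wild type valves neither the distortion nor a joint rise is excluded, since the ranges overlap. The short nuclear genes had a median of -1.52 and an upper quartile of 1.26 there, and the nuclear respiratory genes 0.54 and 0.86. Mitochondrial genes made up 14.4% and 10% of the FPKM sum with long and 32.5% and 35.0% with short telomeres. FPKM divides by transcript length, and the transfer RNA genes have a median of 68 nt, less than the 100 bp of a read. These shares are therefore not shares of reads or of RNA. A difference in RNA quality, library preparation or telomere biology stays open, since the labels give no batch and none of these was tested.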

How the results depend on the processing

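Leaving out genes of other cell types, clone and predicted names or, for correlations, genes called in either comparison was chosen after seeing the data, as were scaling without mitochondrial genes, minimum values of 0 or 1 FPKM, and a pseudocount of 0.1 for lists and correlations. Without the genes of the platelet, thymocyte, neutrophil and erythroid lists, 44 of the 75 called genes were left for Notch1 heterozygous against wild type with long telomeres, and 63 of the 95 for the group with both changes against the group with neither, because fewer genes were counted. The other 3 comparisons stayed within 1.5 times their counts under that setting, and all 5 did with a minimum of 5 FPKM, where 73, 75, 103, 78 and 86 called genes were left. The log2 fold of Notch1 for short against long telomeres in heterozygous valves was -0.10 and turned to 0.14 with median scaling, since the median of all genes had shifted by -0.24. With a mean FPKM of at least 10, 8 lists instead of 13 lay outside the central 95% for the Notch1 genotypes with short telomeres; fewer genes were tested, and the cause was not tested further. Over all comparisons 13 of 135 list results moved inside and 9 outside under that minimum. With a pseudocount of 0.1, 2 of 145 moved inside and 1 outside. Without genes of the other cell types 4 of 140 moved inside. Of 415 log2 folds of named genes 106 moved by more than 1.5 times with a pseudocount of 0.1. The correlation of Notch1 effects lay between 0.025 and 0.035 and that of telomere effects between 0.18 and 0.20 in the 5 settings run for each. No paired analysis was possible because there is 1 pooled value per group. Count normalizations and tests, fits to 2 groups, leaving out single libraries, other false discovery rates, covariates for sex or tissue makeup, set tests and the interaction test were not run, for the same reason. Read depth is unknown, so the level under which a listing at 0 is uninformative cannot be given.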

Other observations

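The lists of haem and iron handling, atrial genes, circadian clock genes and B cells, and the thymocyte stage genes, were tested after the result was seen. Haem and iron handling genes had a median of 1.30 in the group with both changes against the group with neither, with 11 of 12 members higher and Hmox1 and Slc40a1 called in the authors' deposited table. Their medians were 0.18 and 0.81 for the Notch1 genotypes with long and short telomeres, and 0.54 and 0.90 for short against long telomeres in wild type and heterozygous valves. Macrophage and monocyte markers stood beside them with a median of 1.28 for both changes against neither (15 of 17 higher, 0 called), 0.22 and 0.82 for the Notch1 genotypes, and 0.22 (-0.01 as deposited) and 1.02 for the telomere settings in the same order. In these valves Cd36, a fatty acid transporter, was at 53, 111, 351 and 381 FPKM in wild type and heterozygous valves with long telomeres and in the same order with short telomeres. The endothelial genes Aplnr and Thbd stood at 2.54, 4.3, 11.4 and 20.3 FPKM and at 50.6, 96.5, 122 and 215 FPKM.

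Atrial genes had medians of -3.08 and 1.38 for the Notch1 genotypes with long and short telomeres, -2.65 and 2.35 for the telomere settings in wild type and heterozygous valves, and -0.36 for both changes against neither. Sln, a regulator of the calcium pump of atrial muscle, was at 31.4, 0.563, 0.439 and 21.6 FPKM in the same order of groups. Circadian clock genes had medians of -0.79 for short against long telomeres in wild type and -0.82 for both changes against neither, outside the central 95%, and -0.23, -0.01 and -0.10 in the other comparisons. Arntl, a core activator of the clock, stood at 1.72, 13.4, 10.3 and 9.93 FPKM, and Per2, a repressor of it, at 23.8, 11, 5.9 and 9.99 FPKM. The labels used here give no hour of dissection.

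B cell genes had medians of -0.23, 0.21, 0.17, 0.31 and 0.33 in the order of comparisons of the report, all inside the central 95%. The thymocyte stage genes Dntt, Rag1, Rag2, Ptcra and Arpp21 had medians of -3.30 for the Notch1 genotypes with short telomeres, 0.16 and -5.29 for the telomere settings in wild type and heterozygous valves, and -2.07 for both changes against neither. In wild type valves the thymocyte list had a median of 0.62 and a mean of 0.21 for short against long telomeres. Neutrophil genes had medians of 0.50 and -2.33 for the Notch1 genotypes with long and short telomeres. A list of lymphocytes and neutrophils fixed beforehand had medians of 1.54 (3 of 17 called higher) and -0.95 (5 called lower) there. For the telomere settings its medians were 0.63 in wild type (5 called higher) and -0.19 in heterozygous valves (5 called lower). Both changes against neither gave 0.34 (4 called higher, 2 lower). The values of -0.19 and 0.34 lay inside the central 95%. Globin genes made up 3.88% and 1.75% of the FPKM sum in wild type and heterozygous valves with long telomeres and 4.68% and 2.61% with short telomeres.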
